A study of Mus musculus with 8 samples.

How the data were processed

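H4K12la was profiled by CUT&Tag in 8 libraries from mouse brain, 2 each from total cells of WT mice, total cells of 5XFAD mice, microglia of WT mice and microglia of 5XFAD mice. Per the labels' protocols, mice were perfused, whole brains without cerebellum were dissociated mechanically and with enzymes, myelin debris was removed, and microglia were enriched with CD11b-coated beads. Tagmentation used a Tn5 transposase fusion, and libraries were sequenced as paired-end reads. Groups and replicate numbers were taken from the sample titles.

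Per the submitters' processing notes, fastp 0.19.6, Bowtie2 and deepTools were used and the genome build was GRCm38 (mm10). The peak caller, its threshold and any control library are not given in the sources used here. The authors deposited 1 peak list per library with no header, so that peaks appear to have been listed separately for each library. Each line gives a chromosome, a start, an end and a whole-number score. The unit of that deposited score is not stated in the sources used here, and the lowest score was exactly 20 in all 8 lists, so the lists hold only peaks at or above that value. The score is the authors' own value per peak and was used only to rank and filter peaks within one list. It was turned into a percentile within its list, and groups were compared by the presence or absence of peaks. Starts were taken to be counted from 0 and were printed counted from 1. The lists hold no read counts, so depth is unknown and no interval or detection limit that needs it was computed. Longer lists mark more genes, and a longer list can come from more reads as well as from more marked chromatin.

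Gene positions came from a RefSeq gene table of the same build (GRCm38.p6), which gives the start and end of each gene without its strand. The planned promoter window, 2 kb on either side of each transcription start site, therefore could not be drawn, and a gene-end window of 2 kb on either side of both annotated ends of a gene took its place for all results. It includes the 3' end of each gene as well as the 5' end, but no start site more than 2 kb inside the outer ends. In the same way, the planned window of the gene body plus 2 kb upstream became the body plus 2 kb on both sides. A peak was counted when it overlapped a window by 1 base or more, and the share expected at random was computed for peaks of the same widths placed anywhere on these chromosomes. The 21887 protein-coding genes of chromosomes 1 to 19, X and Y were used, and 12616 of them have windows that overlap no window of another such gene. Exons, introns and UTRs were not used here.

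Genes and regions were called one-group when a peak was present in every library of one group and in none of the other, and the count was compared with every other grouping of the same libraries into the same sizes. Consensus regions were made by merging all 8 lists where peaks overlapped by 1 base or more. Similarity was the Jaccard index of covered bases. For each of 16 gene lists, fixed before the data were examined (284 distinct genes, of which 283 matched a protein-coding gene, the exception being Mx1; Sdha is in 2 lists), the share of its genes with a gene-end peak minus the share of all genes in that library was tested. The lists were glycolysis and lactate, hypoxia response, TCA cycle and respiratory chain, disease-associated microglia, inflammatory response, interferon response, histone acylation enzymes, Alzheimer-associated genes, ubiquitous genes, genes of other tissues, and markers of microglia, other leukocytes, neurons, astrocytes, oligodendrocytes and vascular cells. Tests were exact two-sided permutation tests over the 70 assignments of 8 libraries to 2 groups of 4, over the 36 arrangements of genotypes within cell preparations, and over 6 arrangements for 2 against 2, and an exact one-sided permutation over 105 pairings for similarity. Lists among one-group genes were tested with Fisher's exact test, two-sided, against the genes with a peak in at least 1 and not all of the compared libraries. Benjamini-Hochberg adjustment was over the 16 lists, or over all 128 Fisher tests, with a threshold of 0.05.

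The genes named were those in the lists, with examples taken first from members found in every library of one group and none of the other; the up to 10 genes of each one-group set, and the 10 of all 8 libraries, with the highest mean score percentile; and Pkm, Ldha, Hif1a, Thy1, Xist and Y-linked genes as checks. Each list file was compared with every other, and the most exact intervals shared by 2 lists was 193, so no library was counted as a copy of another.

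The overlap code was tested on simulated data, with 0 mismatches against a direct search. In a simulated comparison of microglia with total cells over 21887 genes, 200 genes were planted with a detection probability of 0.95 in microglia and 0.02 elsewhere, and 76.0% of them were recovered as microglia-only, so the rule misses part of the true differences when a library loses a peak by chance. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.

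Alternatives fixed before the data were examined were windows of 1 and 5 kb, gene bodies, the higher-scoring 50% of each list, the same number of peaks from each list (the 22300 highest), autosomes only, an overlap of 50% of each peak, each replicate left out in turn, the replicate number as a block, and all genes as background. A planned threshold on q or p was not run because the files give neither. A score of at least 50 was added in its place after seeing the data, as were genes whose windows overlap no other gene and the use of peak midpoints only.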

Results

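The series profiled lactylation of histone H4 at lysine 12 (H4K12la), an acyl mark derived from lactate, in mouse brain. The assay was CUT&Tag, in which an antibody directs a transposase to the marked chromatin so that DNA beside the mark is cut and sequenced. Wild-type (WT) mice were compared with 5XFAD mice, a model of Alzheimer disease that carries mutated human transgenes under a mouse Thy1 promoter. From each genotype, all cells of the dissociated brain without cerebellum (total cells) and microglia, the resident macrophages of the brain, purified with CD11b beads, were profiled. The 8 libraries form 4 groups of 2. The question was which genes carry the mark in each cell preparation and genotype.

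The 8 peak lists held 25271 and 22543 peaks in total cells of WT mice, 32967 and 22807 in total cells of 5XFAD mice, 22300 and 33500 in WT microglia, and 29947 and 41783 in 5XFAD microglia. Read depth is unknown from these lists, so the absence of a peak means that none was listed and not that the mark was absent. The labels do not say whether the libraries of a group came from separate animals, and p-values therefore measure only the spread between these samples. The smallest p that the exact two-sided permutation tests can give is 0.0286 for 4 libraries against 4, 0.0556 for genotypes within cell types and 0.333 for 2 against 2. No permutation test of genotypes can therefore pass 0.05. A gene is said to have a gene-end peak when a peak overlaps the 2 kb on either side of its annotated start or end. Coordinates are those of GRCm38.

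H4K12la peaks gathered at the ends of protein-coding genes in every library. Gene-end windows make up 5.49% of the chromosomes but held 29.5% to 33.1% of the peaks of each list, 4.52 to 5.61 times the share expected of peaks of the same widths placed at random (5.91% to 6.53%). The rest of the gene bodies held 48.8% to 53.1% of peaks, against 34.4% to 34.7% expected in the same way, and 16.6% to 19.9% of peaks lay elsewhere. Of 21887 protein-coding genes, 3871 (17.7%) had a gene-end peak in all 8 libraries and 9006 (41.1%) in none. Interferon response genes were among the most often marked, with 10 of 14 measured members in all 8 libraries, among them Stat2 and Irf9, which transmit the interferon signal. Genes of the TCA cycle and respiratory chain had 9 of 20 members in all 8 libraries (Sdha, Ogdh and Cycs, for example), and histone acylation enzymes had 7 of 14, including Hdac1, Hdac2 and Kat5. Genes of other tissues had none of 15 in all 8 libraries, and 10 of them, such as the liver gene Alb and the pancreatic gene Ins2, had no gene-end peak in any library. The 10 genes with the highest mean score percentile over all 8 libraries were Lars2, Arl14ep, Ddx60, Sp1, Gtf3c3, Birc3, Acyp2, Zfp975, Trappc6b and Efcab2. Lars2 (gene 102436, chromosome 9, 123366927 to 123462675), a mitochondrial leucyl-tRNA synthetase, led them at 99.9 ± 0.12 (SD, n = 8). No list of artefact-prone regions was applied, and no control library is known here, so signal unrelated to the mark could not be told apart.

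Libraries of one cell preparation resembled each other more, on average, than libraries of different preparations, although the ranges met: indices ran from 0.254 up within a preparation and to 0.272 between preparations, the highest with total cells 5XFAD 1. The mean Jaccard index of covered bases (shared bases over all bases covered by either list) was 0.432 for the 4 pairs within a group, 0.358 for the 8 pairs of one cell preparation and different genotypes, and 0.181 for the 8 pairs of one genotype and different cell preparations. Microglia replicates were closest, at 0.535 in 5XFAD and 0.488 in WT mice, while total cell replicates reached 0.346 and 0.358. Microglia of WT 2 were as close to those of 5XFAD 2 (0.495) as to those of WT 1 (0.488). The mean within groups exceeded that between groups by 0.191 (exact one-sided permutation over 105 ways to pair the libraries, p = 0.00952, the smallest this design can give), a test that does not separate genotype from cell preparation. Total cells of 5XFAD mice overlapped the microglia lists more than those of WT mice did, with mean indices of 0.257 and 0.192 against 0.148 and 0.129. The index cannot exceed the ratio of the shorter to the longer covered length. Lists covered 15.3 to 36.3 Mb in microglia and 7.8 to 14.8 Mb in total cells, which can lower it between preparations. Total cell lists covered 14.8 and 8.63 Mb in 5XFAD mice and 9.63 and 7.8 Mb in WT mice.

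**Figure D1:**
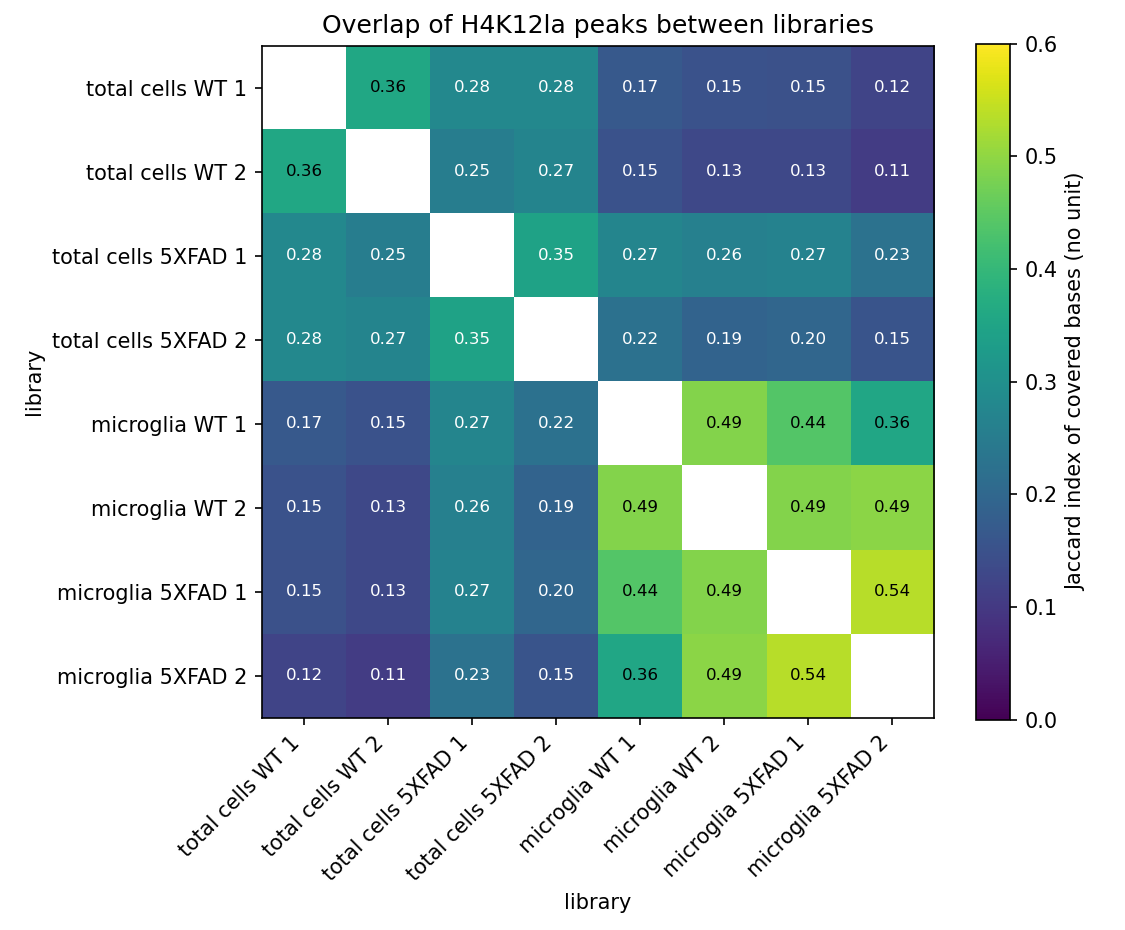
Jaccard index of covered bases (no unit) for each pair of the 8 libraries, with libraries on both axes and the index as colour and number. Pairs of microglia libraries lie between 0.36 and 0.54, and pairs of a total cell and a microglia library between 0.11 and 0.27, the highest of these with total cells 5XFAD 1.

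More microglial markers had a gene-end peak in purified microglia than in total cells. Gene-end peaks were present in all 4 microglia libraries and in no total cell library at 329 genes, and the opposite pattern held at 142 genes. Ptprc (gene 19264, chromosome 1, 138062859 to 138175756), which encodes the leukocyte antigen CD45, had a mean score percentile of 92.8 ± 3.2 (SD, n = 4) in microglia. Ncf1, a subunit of the phagocyte NADPH oxidase, reached 92.5 ± 4.2 and Hcst, a signalling adaptor of leukocytes, 90.5 ± 3.1 (SD, n = 4). The other genes among the 10 highest microglia-only genes were Sppl3, Slc2a9, a urate transporter, Ccdc88b, Ccdc80, Csdc2, Lrrc25 and Hspb3. The 10 highest total-cell-only genes were Camk2g, Tmem14a, LOC100504180, Dnm3, Map2, Fam3c, Rasal2, Atp11b, Mterf2 and Lama2. Camk2g, a calmodulin-dependent kinase, had 95.3 ± 2.9 and Map2 (gene 17756, chromosome 1, 66175202 to 66442583), a structural protein of neuronal dendrites, 87.7 ± 8.7 (SD, n = 4). Of the 68 other ways to choose 4 of the 8 libraries, the highest gave 138 one-sided genes, below both counts. With the same number of peaks from each library the counts were 259 in microglia only and 250 in total cells only, so the imbalance between them depends on list length.

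Markers of microglia showed the widest gap between the preparations. Of the 21 microglial markers, 16 had a gene-end peak in all 4 microglia libraries and 4, such as Spi1 and Cd68, in all 4 total cell libraries. Ctss, C1qb, Selplg, Itgam and Aif1 had one in every microglia library and in no total cell library. The share of the list exceeded the share of all genes by 47.6 ± 2.99 percentage points in microglia and by -1.09 ± 9.47 in total cells (SD, n = 4), a difference of 48.7 (exact permutation p = 0.0286). Disease-associated microglia genes, a programme described around amyloid plaques, were at 38.3 ± 8.33 against 8.2 ± 11.3, and 17 of 25 had a peak in all 4 microglia libraries, among them Trem2, Apoe and Tyrobp. Inflammatory response genes were at 40.8 ± 4.49 against 15.7 ± 1.9, with the cytokine gene Il1b and the inflammasome gene Nlrp3 in microglia only. Alzheimer-associated genes were at 33.3 ± 7.31 against 11.7 ± 9.88 and glycolysis and lactate genes at 25.6 ± 1.94 against 16.1 ± 5.89 (SD, n = 4), Eno2 and Pgam1 of the latter being found in microglia only. Each of these differences had an exact permutation p of 0.0286, adjusted to 0.0762 by Benjamini-Hochberg over the 16 lists. This smallest possible p passes the adjustment only when most of the 16 lists reach it together. Thus 0 lists passed after adjustment and 6 passed without it. The sixth was the list of ubiquitous genes, at 36.7 ± 7.42 in microglia against 21.5 ± 3.11 (SD, n = 4), and with equal numbers of peaks the glycolysis difference was 3.35 (exact permutation p = 0.457) and the Alzheimer difference 13.7 (exact permutation p = 0.0857).

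Markers of the other cell types stayed below the share of all genes in both preparations. Neuronal markers were at -31.1 ± 6.43 percentage points in microglia and -19.7 ± 6.89 in total cells (exact permutation p = 0.0571, n = 4 each), with 11 of 19 (Snap25 and Syt1, for example) lacking a gene-end peak in every library. Astrocyte markers were at -16.7 ± 3.98 and -13.6 ± 5.91, oligodendrocyte markers at -26.7 ± 4.57 and -28.5 ± 0.963, and vascular markers at -18.3 ± 6.31 and -25.1 ± 3.11 in microglia and total cells (exact permutation p from 0.0857 to 0.714, n = 4 each). Mbp, a myelin protein gene, had a gene-end peak in all 4 microglia libraries and in no total cell library. Other leukocytes, some of which the CD11b beads also bind, were at -28.3 ± 4.52 against -35.1 ± 5.72 (exact permutation p = 0.114, n = 4 each), and 11 of their 15 markers, including Cd163, Ccr2 and S100a9, had no gene-end peak in any library. The remaining lists differed between microglia and total cells by -6.65 points for interferon response, -11.5 for genes of other tissues, 8.29 for hypoxia response, -2.37 for the TCA cycle and -3.08 for histone acylation enzymes (exact permutation p from 0.0571 to 0.771, n = 4 each).

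**Figure D2:**
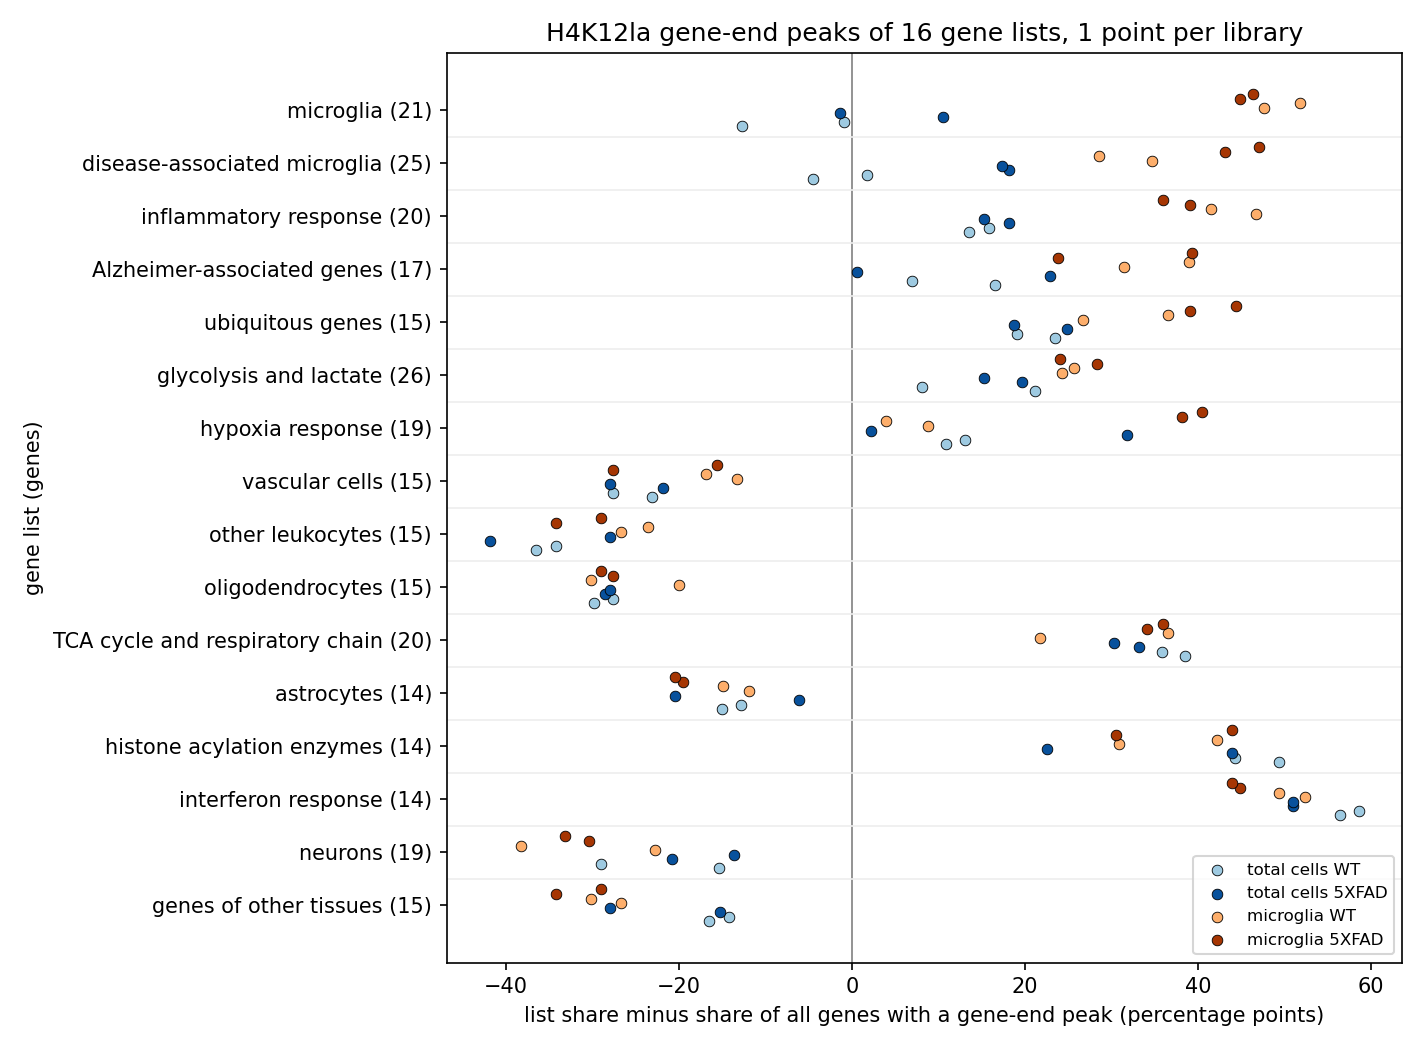
Share of each list's genes with a gene-end peak minus the share of all genes in the same library, in percentage points on the horizontal axis, for 16 gene lists on the vertical axis with their numbers of genes. Each point is 1 library, coloured by group, and points of a list are shifted vertically only to keep them apart. All 4 microglia libraries lie between 44.8 and 51.8 for microglial markers and all 4 total cell libraries between -12.7 and 10.5.

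Tested as whole sets, the microglia-only genes held 5 of the 17 microglial markers that varied between libraries (29.4%) against 3.65% of all varying genes (Fisher's exact test, p = 0.000271, adjusted p = 0.0347). This was 1 adjusted call among 128 such tests, with 5 unadjusted, and genes are not independent replicates. No list passed with windows of 5 kb, gene bodies, the higher-scoring 50% of peaks, genes whose windows overlap no other, or peak midpoints, nor without total cells WT 1, total cells 5XFAD 2 or microglia 5XFAD 1. Peaks themselves differed in width: the median width was 648 ± 64.7 bp in microglia and 321 ± 33.0 bp in total cells, and the lists covered 25.0 ± 8.78 and 10.2 ± 3.15 Mb (SD, n = 4, exact permutation p = 0.0286 for both). The test of covered length, unlike that of median width, did not pass when any 1 total cell library was left out. The narrowest peak of each list was 273 to 289 bp in microglia and 172 to 195 bp in total cells. Fragment lengths and peak-calling settings are unknown here, so a technical difference between the preparations could not be told apart from one in the mark. This limit holds for every contrast of the preparations. The number of peaks (31882 ± 8090 against 25897 ± 4870), of genes with a gene-end peak (9121 against 8056 on average) and the gene-end share of peaks (30.6% against 31.9%) could not be distinguished between the preparations (exact permutation p = 0.286, n = 4 each). With equal numbers of peaks the gene-end share differed by -1.24 points, with the higher-scoring 50% of peaks by -7.43 and with a score of at least 50 by -7.96 (exact permutation p = 0.0286 for each, n = 4 each).

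Among the microglia libraries, 697 genes had a gene-end peak in both 5XFAD and neither WT library, and 127 genes had the opposite pattern. With equal numbers of peaks the counts were 491 and 389. The first set held 5 genes of the hypoxia response, a list that did not pass its tests. Egln2, an oxygen-sensing hydroxylase, Epas1, which encodes the transcription factor HIF-2 alpha, and the hypoxia targets Adm, Bnip3 and Ero1a had gene-end peaks in both 5XFAD and in neither WT microglia library. In total cells, Ero1a had a gene-end peak in every library and Adm and Epas1 in both WT libraries and 5XFAD 1. Egln2 had one there in every library but WT 1, and Bnip3 in 5XFAD 1 only. The list exceeded the share of all genes by 39.3 ± 1.73 percentage points in 5XFAD and 6.32 ± 3.45 in WT microglia (SD, n = 2), and in total cells by 17.0 ± 21 and 12 ± 1.58. Over both preparations the difference was 19.0 points (exact permutation p = 0.167, adjusted p = 0.889), and with windows of 1 kb it was 8.64, with 17.4 in microglia. With equal numbers of peaks the list stood at 39.6 and 1.84 points in the 5XFAD and at 8.76 and 2.45 in the WT microglia libraries, so the difference then rested on 5XFAD 1, and with the higher-scoring 50% of peaks it was -0.535 in microglia. The 5 genes were 5 of the 10 varying members of the list (50%) against 13.9% of all varying genes (Fisher's exact test, p = 0.00694, adjusted p = 0.444).

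Disease-associated microglia genes were at 45.1 ± 2.77 points in 5XFAD and 31.6 ± 4.34 in WT microglia (SD, n = 2). The lysosomal protease gene Ctsd, the lysozyme gene Lyz2 and the growth factor gene Igf1 had a gene-end peak in both 5XFAD and neither WT microglia library, 3 of 7 varying members (Fisher's exact test, p = 0.0602, adjusted p = 1.0). Ubiquitous genes were at 41.7 ± 3.71 and 31.6 ± 6.97 points in the same libraries (SD, n = 2). Over both preparations the disease-associated list was 16.3 points higher in 5XFAD mice (exact permutation p = 0.0556, the smallest possible, adjusted p = 0.444). The difference was 10.3 points with equal numbers of peaks, and with a score of at least 50 it was 8.69 (exact permutation p = 0.0556 and 0.111). The 10 highest 5XFAD-only genes among microglia libraries were Gm5796, Gm7102, Thy1, Efr3b, Qpct, Iqce, the neighbours Apoc2 and Gm44805, 9930111J21Rik2 and Sft2d3. Gm5796, Gm7102, Iqce and 9930111J21Rik2 had no gene-end peak in total cells, while Sft2d3 had one in all 4 total cell libraries. Qpct (gene 70536, chromosome 17, 79051906 to 79090378), the glutaminyl cyclase that forms pyroglutamate at protein ends, had a score percentile of 90.6 ± 0.61 (SD, n = 2). The highest WT-only genes among microglia libraries were Pnp2, Tmem192, Gm3239, Zfp12, Gm3264, Rcn2, Gpr75, Klf7, Cfap97d1 and Tmem170. Pnp2, a purine nucleoside phosphorylase, was at 90.7 ± 6.1 (SD, n = 2). Pnp2, Tmem192, Zfp12, Rcn2, Gpr75 and Tmem170 also had a gene-end peak in all 4 total cell libraries, and Gm3264 and Cfap97d1 in none. Another pair of microglia libraries, WT 2 and 5XFAD 2, which had the longest lists, shared 542 genes that the other 2 lacked, and without WT 2 the 5XFAD count was 2215.

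In total cells, 681 genes had a gene-end peak in both 5XFAD and neither WT library, and 358 in both WT and neither 5XFAD library. The mixed pair of WT 1 and 5XFAD 1 shared 394 genes in the same way, more than the WT pair, and without 5XFAD 1 the counts were 1007 in 5XFAD and 1041 in WT. These counts were 567 and 474 with equal numbers of peaks. Many genes of the first set also had peaks in purified microglia. P2ry12 and P2ry13, purinergic receptors of resting microglia, and the disease-associated genes Tyrobp, Axl, Lpl and Lyz2 were among them, and 340 of the 681 genes (49.9%) had a gene-end peak in all 4 microglia libraries, against 80 of the 358 WT genes (22.3%; Fisher's exact test, odds ratio 3.46, p = 2.48e-18, genes not being independent replicates). Of all genes, 29.4% had a gene-end peak in all 4 microglia libraries. The first set held 2 of 8 varying microglial markers and 4 of 12 varying disease-associated genes, both more than its share of all varying genes. Neither list passed adjustment (Fisher's exact test, p = 0.217 and 0.0348, adjusted p = 1.0 for both). So few genes leave enrichment undecided. For the other 4 pairs of total cell libraries the share with a gene-end peak in all 4 microglia libraries was 21.7% to 36%. The difference between the sets, 27.6 percentage points, was 5.19 without 5XFAD 1 and 9.13 without 5XFAD 2. The disease-associated list was at 17.7 ± 0.591 points in 5XFAD and -1.35 ± 4.41 in WT total cells, and microglial markers were at 4.59 ± 8.4 and -6.77 ± 8.31 (SD, n = 2). Astrocyte markers stood at -13.3 ± 10.1 and -13.9 ± 1.58 in the same libraries.

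The 10 highest 5XFAD-only genes among total cell libraries were Thy1, Gm14410, Grb2, Bdp1, Plk4, Gm40369, the neighbours Dis3 and Pibf1, Qdpr and Gm14305. Grb2 (gene 14784, chromosome 11, 115644045 to 115708597), an adaptor of growth factor receptors, had a percentile of 97.2 ± 1.6 (SD, n = 2). The 10 highest WT-only genes were the neighbours 1810030O07Rik and Med14, Sf3b6, Nfatc2ip, Flad1, Thoc3, the neighbours Golph3l and Hormad1, Nmrk1 and Pcx. Med14 (gene 26896, chromosome X, 12675368 to 12762594), a Mediator subunit, had 96.2 ± 1.6 (SD, n = 2). Many of these genes also had a gene-end peak in all 4 microglia libraries. Among the 5XFAD-only genes these were Grb2, Plk4, Gm40369 and Qdpr, while Gm14410 and Gm14305 had one in none. Among the WT-only genes they were 1810030O07Rik, Med14, Sf3b6, Nfatc2ip and Flad1. Among glycolysis genes in total cells, Gapdh and the lactate transporter gene Slc16a3 had a gene-end peak in 5XFAD mice only, and Pkm in WT mice only. The Slc16a3 peak was at percentiles of 72.6 and 4.6 in total cells 5XFAD 1 and 2, the latter near the bottom of its list. In microglia, Slc16a3 and Pkm had a gene-end peak in all 4 libraries and Gapdh in 3. The list as a whole was at 17.5 ± 3.09 and 14.7 ± 9.3 points in 5XFAD and WT total cells and at 26.2 ± 3.0 and 25.0 ± 0.99 in microglia (SD, n = 2). Its genotype difference over both preparations was 2.01 points (exact permutation p = 0.667).

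**Figure D3:**
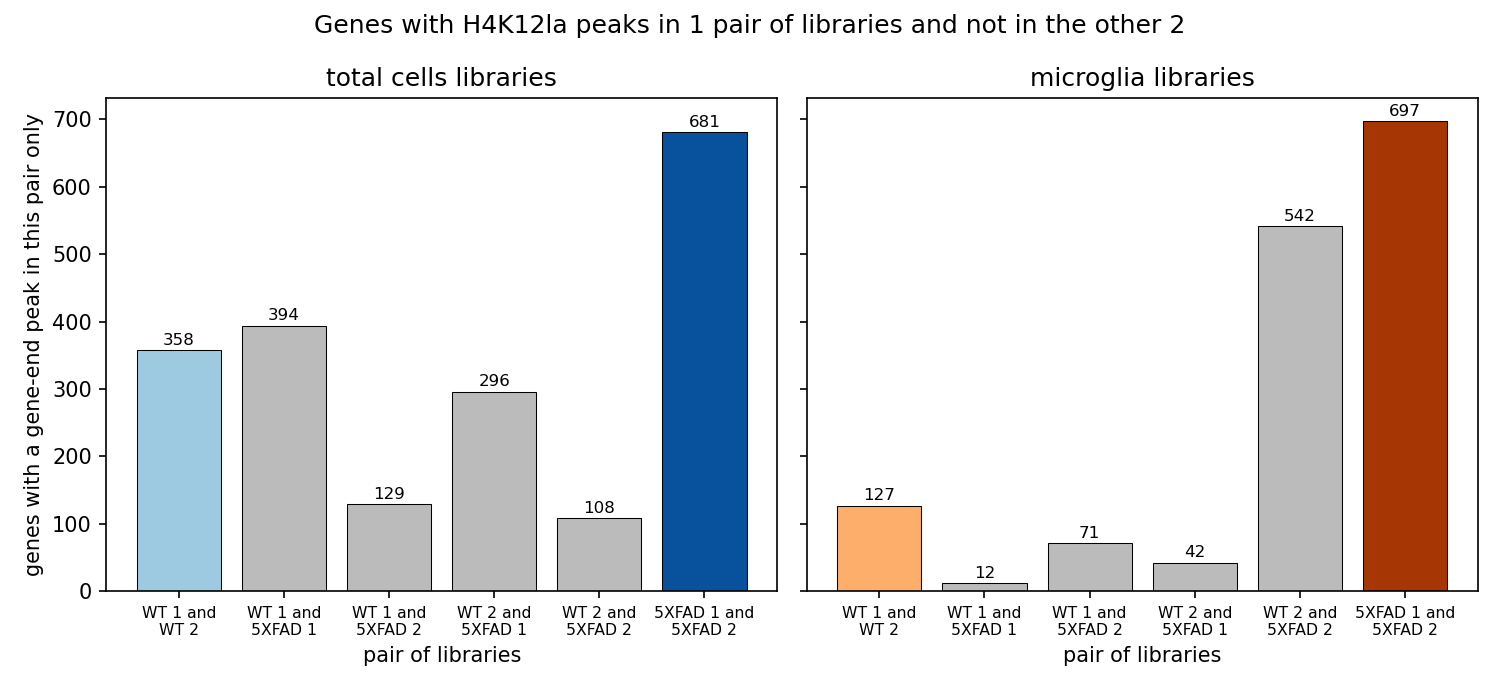
Number of genes with a gene-end peak in both libraries of a pair and in neither of the other 2 libraries of the same preparation (vertical axis, genes), for each pair of total cell (left) and microglia (right) libraries on the horizontal axis. Coloured bars are pairs of one genotype and grey bars mixed pairs; the 5XFAD pairs reach 681 and 697 genes, and the mixed microglia pair WT 2 and 5XFAD 2 reaches 542.

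The genotype difference in a list was not shown to depend on the cell preparation. For hypoxia genes it was 33.0 points in microglia and 4.98 in total cells (exact permutation test of the difference, p = 0.222, adjusted p = 0.741). No list passed this test, with adjusted p from 0.741 up. Interferon response genes differed by -6.51 points between 5XFAD and WT mice relative to all genes (exact permutation p = 0.0556), with 12 or 13 of the 14 members having a peak in each library. The difference was -0.661 with equal numbers of peaks and with the higher-scoring 50% of peaks 8.26. Ubiquitous genes differed by 5.28 points, inflammatory genes by -2.22, Alzheimer-associated genes by -1.78, TCA cycle genes by 0.28, histone acylation enzymes by -6.51 and genes of other tissues by -4.72 between 5XFAD and WT mice (exact permutation p from 0.222 to 1.0). The marker lists differed by 3.61 points for microglia, -3.05 for other leukocytes, 1.86 for neurons, -2.93 for astrocytes, -1.39 for oligodendrocytes and -3.05 for vascular cells (exact permutation p from 0.5 to 0.889). Numbers of peaks, of marked genes and the gene-end share could not be distinguished between genotypes either (exact permutation p from 0.278 to 0.389).

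Across both preparations, 38 genes had a gene-end peak in all 4 5XFAD and no WT library, and 6 in all 4 WT and no 5XFAD library. With equal numbers of peaks these counts were 30 and 16. Among genes that varied in both preparations, the sets of 5XFAD microglia and of 5XFAD total cells shared 38 genes, close to the 40.1 that independent sets would share (Fisher's exact test, p = 0.787). The 10 highest were Thy1, Bdp1, Tank, Casc3, Ankrd46, Lyz2, the overlapping Tmsb15b1 and Tmsb15l, Dcaf12 and Zfp947. Tank, a regulator of interferon and NF-kappa-B signalling, had a mean percentile of 80.6 ± 1.7 and Lyz2 of 71.6 ± 21 (SD, n = 4). The 6 WT genes were the neighbours Ccs and Ccdc87, Akap12, Rnd3, Ccdc150 and Hp1bp3, at percentiles of 19.8 to 45.9.

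Thy1 (gene 21838, chromosome 9, 44043384 to 44048579), a surface glycoprotein gene of neurons whose promoter drives the 5XFAD transgenes, was the clearest difference between genotypes. Each of the 4 5XFAD libraries had 4 peaks there and each WT library had 0. These peaks could come from reads of the transgenes as well as from the endogenous gene. Peak edges shared between libraries, given below, lean towards the transgenes without excluding the endogenous gene. In total cells 5XFAD 1 the peaks ran from 44042141 to 44050046, and in the 4 libraries they spanned 7.82 to 7.91 kb and left a gap inside the gene of 2.1 to 3.18 kb without a peak. In total cells the Thy1 peaks were among the highest of the list, at percentiles of 99.9 to 100, and in microglia at 63.1 to 93.9. No other neuronal marker of the list had a gene-end peak in both 5XFAD and neither WT microglia library.

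**Figure D4:**
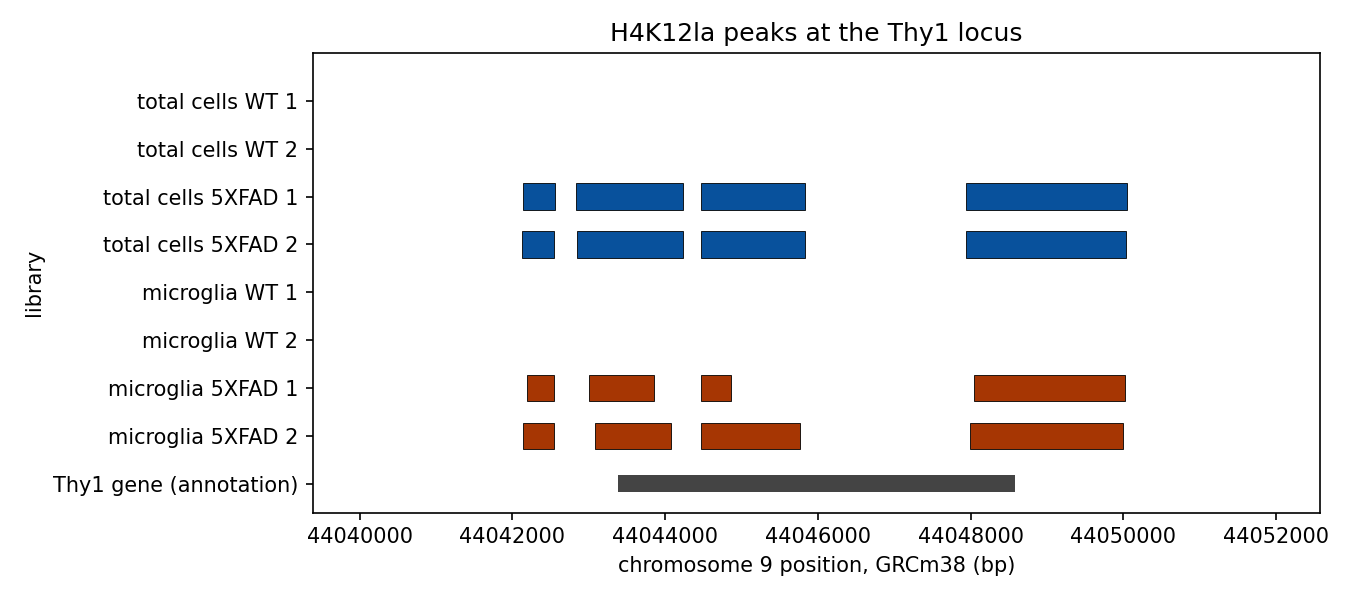
Peaks at the Thy1 locus on chromosome 9 (horizontal axis, GRCm38 position in bp) in the 8 libraries (vertical axis), with each bar drawn from the start to the end of a peak and the annotated gene in grey. The 4 5XFAD libraries have 4 peaks each with a shared gap from about 44045835 to 44047936, and the 4 WT libraries have none.

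Pkm, Ldha and Hif1a, the genes of a glycolytic enzyme, of lactate dehydrogenase A and of the hypoxia factor HIF-1 alpha, were examined by name. Pkm (chromosome 9, 59656576 to 59679372) had a peak at its lower end, within 59655990 to 59656670, in both WT total cell libraries and all 4 microglia libraries, and no peak in 5XFAD total cells. Ldha (chromosome 7, 46842274 to 46855627) had no gene-end peak in any library but a peak inside the gene, starting between 46845751 and 46846731, in 6 of 8 libraries. Hif1a (chromosome 12, 73901324 to 73947554) likewise had no gene-end peak and a peak inside the gene, starting between 73906971 and 73907538, in all 8 libraries. Its percentiles were 87.2 and 83.5 in WT and 92.2 and 94.0 in 5XFAD microglia. In total cells they were 87.8 and 83.7 in WT and 88.6 and 92.3 in 5XFAD mice. None of these 3 genes differed between the genotypes in microglia by presence of such a peak in both libraries of one and neither of the other. Presence cannot show a change at a peak that every library has, and the higher Hif1a percentiles of 5XFAD libraries were not tested. The windows follow only the outer annotated ends, so a start site further inside a gene would be missed. The inner peaks of Ldha and Hif1a may therefore mark a start site, and this was not tested. No library had a peak at Xist, and 7 of 8 had a peak at 1 or more of the Y-linked genes Kdm5d, Eif2s3y, Uty and Ddx3y, the exception being total cells WT 1.

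Merging all lists gave 73400 regions, of which 27816 (37.9%) were found in 1 library and 5288 (7.2%) in all 8. Microglia alone held 3307 regions and total cells alone 984. The highest microglia-only region lay near Arl10 (chromosome 13, 54577648 to 54579275) and the next near Ehd4 (chromosome 2, 120096330 to 120097398), and the highest total-cell-only region near Nwd1 (chromosome 8, 72698397 to 72698846). Over both preparations, 220 regions were found in 5XFAD alone and 18 in WT alone, with 4 of the 6 highest 5XFAD regions at Thy1, and with equal numbers of peaks the counts were 143 and 39. Another lay near Umad1 (chromosome 6, 8412743 to 8413251). The 16732 regions shared by all 4 microglia libraries were found in 71.5% and 58.5% of cases in total cells of 5XFAD mice and in 47.0% and 43.7% in those of WT mice (exact permutation p = 0.333, the smallest possible for 2 against 2).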

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

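The tests at Thy1, of the loss of other cell types, of hypoxia genes and of other splits for gene-end peaks were chosen only after the result was seen; those of peak number in total cells and of other splits for regions were written before.

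The results below met the rules for a closer look, as a signal outside the main measurement or as a difference between groups. Total cells of 5XFAD mice had 36 and 32 peaks on unplaced sequences, which the comparisons of genes leave out and those of regions include, against 30 and 31 in WT total cells. Their lists held 32967 and 22807 peaks in all, against 25271 and 22543, so relative to list length the genotypes overlapped. In 19 genes the genotypes differed in opposite directions, with a gene-end peak in both 5XFAD and no WT microglia library but in both WT and no 5XFAD total cell library: Plcg1, Hormad1, Golph3l, Crocc, Ctnnbip1, Pitpnm2, Tsc22d4, Fbxl18, Prkaca, Dhps, Yipf2, Sgsm2, 1700020L24Rik, Akt1, Ccar2, Mtmr12, Sco2, Itpr3 and Nmrk1. In 3 genes, Gmeb2, Slc31a2 and Ednrb, the directions were the other way round. The difference itself was not tested for single genes, and independent sets would share 21.8 and 6.76 genes (Fisher's exact test, two-sided, p = 0.633 and 0.149).

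Peaks at Thy1 in 5XFAD libraries only could come from reads of the transgenes, which carry Thy1 sequence, or from the endogenous gene. Of the 18 other neuronal markers, 0 had a gene-end peak in both 5XFAD and no WT microglia library, which the transgene explanation needs but which would also be seen if the endogenous gene alone had changed. Peaks within 50 kb outside the Thy1 peaks were found in 3 libraries of each genotype, a difference of 0, which does not decide on the endogenous gene. The peaks also left an inner gap of 2.1 to 3.18 kb in every 5XFAD library, which the transgene explanation needs too. A gap alone does not exclude the endogenous gene. A Thy1 peak began at the same base, 44044473, in every 5XFAD library, and another ended at 44042549 or 44042554 in each. Edges fixed to the base would follow from a transgene copy with set ends, and argue against a change of the endogenous gene alone. They do not exclude it. An Eif2s3y peak also shared its start, 1010290, between total cells 5XFAD 2 and both WT microglia libraries. H4K12la on the transgenes themselves would look the same as other reads from them. Read sequences, which could tell the copies apart, were not analysed here.

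Total cells of 5XFAD mice held more of the regions that all microglia libraries share. A longer list does not account for this, since with equal numbers of peaks the lower 5XFAD library was still 15.5 percentage points above the higher WT library. A loss of other cell types from the suspension stays open: the median change of the astrocyte, oligodendrocyte and vascular markers was 0.036 of the microglial change, but most of these markers had no gene-end peak in any library, and a loss of these cells would lower them, so this decides nothing. The microglial markers themselves overlapped between the genotypes (10.5 and -1.35 points in 5XFAD, -12.7 and -0.897 in WT). A larger share of microglia, or more H4K12la in them, in 5XFAD brains may be the biological reading, and neither was tested here.

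Hypoxia genes in 5XFAD microglia may reflect list length, since 5XFAD 2 had the longest list of all, 41783 peaks. With equal numbers of peaks the lower 5XFAD library was -6.93 points from the higher WT library, while 5XFAD 1 kept 39.6 points, so the 2 libraries part. The 5 genes that set the list apart had peaks at score percentiles of 25.1 to 67.3 in 5XFAD microglia. Whether list length or the genotype is the reason cannot be told.

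Other splits of the 8 libraries into 4 and 4 bear on how firmly each grouping stands. Of 35 splits, only 1, the real one between microglia and total cells, gave as many one-sided genes (471, against at most 139 otherwise), and 1 gave as many one-sided regions (4291, against at most 633). The split by genotype gave 44 genes, and 7 splits gave as many or more, while for regions it gave 238 and 4 splits gave as many or more, so chance is not excluded. All the other splits that reached the genotype counts had unequal numbers of microglia libraries on their sides, so they also part the preparations. Among the 18 splits with 2 microglia libraries on each side the genotype split was the highest (next 28 genes and 122 regions), but 18 are too few for a share under 0.05.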

How the results depend on the processing

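The tests of gene-end windows alone, peak midpoints and a score of at least 50 were chosen only after the result was seen; the other alternatives were fixed before the data were examined, and a threshold on q or p was not run. Of 660 alternative values, 534 kept their direction and side of the threshold or stayed near the main value, 72 moved, 39 became weaker, 4 became stronger and 11 reversed. This tally does not measure stability, since permutation tests of genotypes could not pass the threshold in any setting and large moves on one side of it are counted as kept. Read depth is unknown, so what it limits could not be assessed, and 2 libraries per group leave each genotype count open to a single library. Microglial markers (44.1 to 57.1 points), disease-associated microglia genes (23.5 to 37.5) and inflammatory genes (21.6 to 29.8) stayed higher in microglia in every setting. Similarity within groups exceeded that between groups by 0.158 to 0.227. None of the 16 lists passed after adjustment in the tests of list shares in any setting. For the preparations this was close to fixed beforehand, since the smallest p of 0.0286 passes adjustment only when most of the 16 lists reach it together. Numbers below concern genes with a gene-end peak unless regions are named; where peaks or genes are removed the counts move by construction, and otherwise the cause was not tested.

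Replicate numbers 1 and 2 as a block left the values unchanged, but with 16 arrangements the smallest exact permutation p is 0.125, which is what median width (327 bp) and covered length (14.76 Mb) then had. Correlations between deviations of libraries with the same number ran from -0.051 to 0.12, highest between WT and 5XFAD microglia, where both libraries numbered 2 had the longer lists, so whether the numbers pair the libraries is not settled.

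With the same number of peaks from each library, the cell preparations differed by -100.8 marked genes and -1.235 points of gene-end share, and the genotypes by 0.3655 points. Counts were 389 genes in WT microglia only, 250 in total cells only and 16 in WT only over both preparations, and 143 regions in 5XFAD only and 39 in WT only.

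With a score of at least 50, the gene-end share differed by -7.958 points between preparations and interferon genes by 2.613 between genotypes. Counts were 77 genes in WT microglia only, 72 in total cells only and 3 in WT only, and 48696 regions, with 426 in total cells only and 6 in WT only. With the higher-scoring 50% of peaks, the gene-end share differed by -7.43, glycolysis genes by -3.28 and interferon genes by 8.259 between genotypes, and hypoxia genes by -0.5348 between genotypes in microglia. Counts were 64 genes in 5XFAD only, 3 in WT only and 0 lists among one-group genes, and 36387 regions, with 1981 in microglia only, 145 in 5XFAD only and 4 in WT only.

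With windows of 5 kb, the gene-end share differed by 0.02246 and 0 lists passed among one-group genes. With gene bodies plus 2 kb, the share differed by -2.004 between preparations and 0.248 between genotypes, 215 genes were in total cells only and 0 lists passed. With genes whose windows overlap no other, counts were 305 in 5XFAD microglia only, 74 in WT microglia only, 300 in 5XFAD total cells only, 154 in WT total cells only, 149 in microglia only, 82 in total cells only and 18 in 5XFAD only, with glycolysis at -5.294 and interferon at 0.9565 between genotypes and 0 lists. With peak midpoints 0 lists passed, and with all genes as background 2. With an overlap of 50% of each peak, 5245 regions were in microglia only.

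Leaving out each replicate in turn, and so making the one-group rule easier to meet, gave 697 to 2215 genes in 5XFAD microglia only, 127 to 571 in WT microglia only, 681 to 1615 in 5XFAD total cells only, 358 to 1041 in WT total cells only, 334 to 597 in microglia only, 149 to 232 in total cells only, 42 to 154 in 5XFAD only and 7 to 23 in WT only. Regions numbered 3368 to 5575 in microglia only, 1022 to 1969 in total cells only, 249 to 670 in 5XFAD only and 20 to 106 in WT only. Covered length differed by 10.98 to 17.97 Mb, glycolysis genes by -1.278 to 5.3 points between genotypes, and 0 to 1 lists passed among one-group genes.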

Other observations

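The test of gene families was written before the result was seen. Families of genes that share a name differed widely in how often every library had a gene-end peak, a test against the hypothesis that marking is even across families. Of 56 families with at least 30 members, 20 differed from all other genes (Fisher's exact test, two-sided, adjusted p below 0.05), 7 of them being more often marked than the 17.7% of all genes. Families here are shared name prefixes only, so the 20 include LOC, a prefix of unnamed genes and not a family (Fisher's exact test, adjusted p = 0.00385). Zinc finger genes named Zfp, most of which encode DNA-binding proteins, had a peak in all 8 libraries in 176 of 397 members (44.3%, Fisher's exact test, adjusted p = 5.14e-34), and the mitochondrial ribosomal genes named Mrpl in 24 of 49 (49.0%, adjusted p = 7.32e-06). Genes named Cep, of the centrosome, had 16 of 38 (42.1%, Fisher's exact test, adjusted p = 0.00266) and those named Rab, GTPases of vesicle traffic, 23 of 69 (33.3%, adjusted p = 0.0102). Genes named Snx and Med, the latter of the Mediator complex, had 11 of 30 each (36.7%), and those named Ppp 22 of 77 (28.6%).

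Olfactory receptor genes named Olfr had 0 of 1110 members marked in all 8 libraries, and 1099 (99.0%) lacked a gene-end peak in every library. Vomeronasal receptor genes named Vmn had 1 of 355, keratin genes named Krt 0 of 53, collagen genes named Col 1 of 44 and cytochrome P450 genes named Cyp 8 of 99 (8.08%, Fisher's exact test, adjusted p = 0.0374). Family members often lie side by side, so that genes are not independent and these p-values are too small.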
